A study of Mus musculus with 9 samples.

How the data were processed

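Gene expression was measured by 3′ end mRNA sequencing in 9 libraries of normal mammary fibroblasts, sorted after monoculture for 5 days or co-culture with 4T1-GFP carcinoma cells for 3 or 5 days, with 3 libraries in each group. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, aligned with STAR 2.4.2a to mm10 and counted with HTSeq, and the annotation, the strand setting, the filter on genes and the way library factors were set are not stated. The authors deposited normalised gene counts, a signal on a count scale in which each library's counts were divided by a factor of its own and rounded to 1 decimal. Nothing in the labels says whether the replicates were separate cultures or animals. Columns were matched to samples by their names; the column taken as replicate 2 of the 5-day co-culture names no carcinoma cells, and it was placed there because the other 8 columns account for every other sample. The table held 11931 genes, 18 of them with names that a spreadsheet had turned into dates, 1 with a value of 0 in every library, and 0 mitochondrially encoded genes.

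Low values in each library were whole multiples of what 1 read is worth, between 0.481 and 1.66 units, so whole reads were recovered by division. Between 99.81% and 99.97% of a library's values came out whole within a tolerance of 0.051. The recovered totals lay between 1048471 and 3567326 reads, and the monocultures were deeper (mean 2966627) than the co-cultures at 3 days (1632228) and 5 days (1806567). Reads without molecular identifiers are not independent molecules, so counting intervals and floors cover counting error only.

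The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2(value + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes with a value of at least 5 in at least 3 of the 9 libraries were tested, 10639 in all, leaving out 1292. All 9 libraries entered 1 model with a mean for each of the 3 groups. Log2 fold changes are on the log2(value + 1) scale and understate the change of low genes. For a gene with 0 reads in a group the fold was computed against a floor of 3 counts over the group, and for 1 to 3 reads the ratio of reads, scaled by what a read is worth, is given with an exact Clopper-Pearson 95% interval. Runx1, Runx2, Cbfb and Pdpn were also compared with the exact two-sided permutation test of 3 against 3 values, whose smallest p is 0.1.

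Before the data were examined, 28 gene lists and 9 lists of cell type markers were fixed, with the tests, the comparisons, the alternatives and a rule for the genes named in the text. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists with at least 3 tested members, beside camera with an estimated correlation and fry. Camera sets the members of a list against the other genes, whereas fry asks only whether the members changed together. Fry passed some lists that camera did not, and apart from those named in the text its results are not reported here. The rule took, per comparison, the RUNX genes, Cbfb and Pdpn, the 8 largest rises and 8 largest falls among called genes with a mean of at least 10 and no overlap between groups, up to 3 called members of each list by the smallest adjusted p (or, where none was called, its highest member), and the 2 highest members of each marker list. Of these, the text names a selection made after the values were seen, with lists taken first by the smallest camera p, and some genes that the rule took are not reported here. Gene positions are from GENCODE M21 on mm10, with 79 of 82 named genes matched by symbol; Figf, Nov and Ctgf are older symbols and have no position here. Reads of near-identical genes, such as those of class I antigen presentation, could have been split or lost in counting.

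Alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 20, median-of-ratios and TMM rescaling, quantile normalization, a replicate block, a fit of only the compared groups, an added 2-fold threshold, array weights, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. A further alternative, chosen after seeing the data, thinned the reads of every library at random to the depth of the shallowest. The correlation, covariance and shared calls that the shared monoculture libraries bring without any change came from 50 simulations of unchanged groups. The scripts were tested on simulated reads with 200 changed genes. In the simulation of 3-day co-culture against monoculture, with 10183 genes, limma recovered 6.38%, 44.9%, 89.1% and 93.9% of the genes changed 1.5-, 2-, 4- and 8-fold, and 10 of 122 calls were unchanged genes. In that of 5-day co-culture against monoculture, with 10164 genes, the shares were 6.38%, 23.4%, 86.0% and 98.0%, with 7 unchanged genes among 112 calls. In that of 5 against 3 days, with 10298 genes, they were 4.26%, 30.4%, 93.9% and 93.9%, with 6 among 114. In these simulations most changes of 1.5- and 2-fold were thus missed. Limma called 2129, 2552 and 735 genes in the real comparisons, more than the 200 changed here. The adjusted threshold was therefore less strict in the data, and the simulated shares do not carry over to them.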

Results

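Normal mammary fibroblasts were isolated from the fat pads of 12-week-old female BALB/c mice, allowed 1 week to recover on collagen, and grown alone for 5 days or together with 4T1-GFP cells for 3 or 5 days. 4T1 is a mouse mammary carcinoma cell line of BALB/c origin, here carrying green fluorescent protein (GFP). Fibroblasts were separated from the carcinoma cells by sorting for cells without GFP and with podoplanin, a surface glycoprotein encoded by Pdpn. Then 3′ end mRNA libraries were sequenced. The 9 libraries formed 3 groups of 3: monoculture for 5 days, co-culture for 3 days and co-culture for 5 days. The deposited table gave normalised read counts for 11931 genes, of which 10639 were tested. Reads assigned to genes, recovered from the values, numbered 2708643, 3567326 and 2623911 in the monoculture libraries, 1048471, 2579766 and 1268448 after 3 days of co-culture, and 1987168, 1973151 and 1459381 after 5 days. The first principal component of the log2 values, with 47.7% of the variance, separated the monocultures from every co-culture library, and the next, with 16.4%, separated the days of co-culture.

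**Figure D1:**
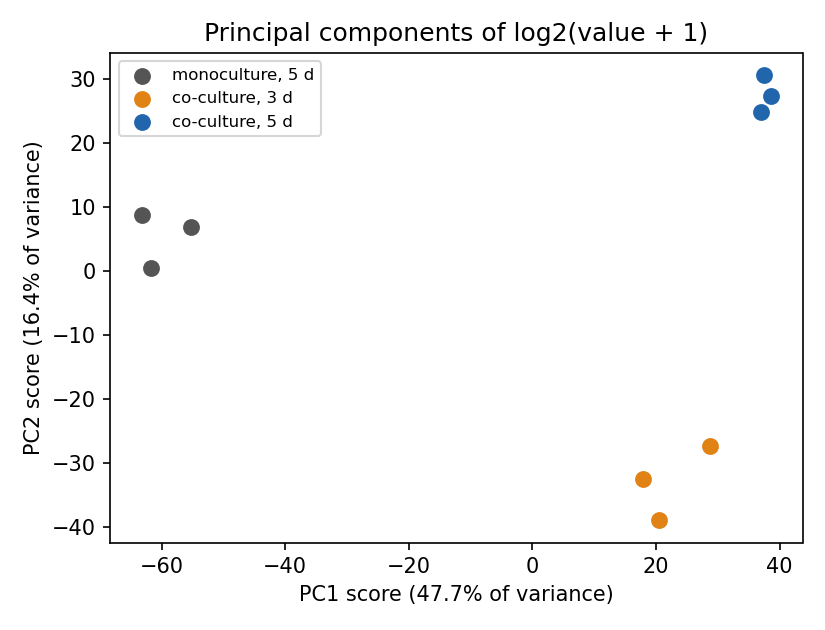
Scores of the 9 libraries on the first principal components of log2(value + 1), without units, with a point per library coloured by group. The monoculture libraries lie between -63.2 and -55.3 on the first component, and all co-culture libraries lie between 17.8 and 38.6.

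The title of the series links altered DNA methylation in cancer-associated fibroblasts with higher RUNX1, and the co-culture design asks how normal fibroblasts change next to carcinoma cells. Runx1 (chromosome 16, 92601466 to 92826149, minus strand, mm10, a protein-coding gene) had normalised counts of 162.2, 206.2 and 107.3 in the monocultures, 96.3, 123.9 and 129.4 after 3 days of co-culture, and 204.0, 161.1 and 187.3 after 5 days. Runx1 did not pass the test in any comparison. Its log2 fold change against monoculture was -0.40 at 3 days (95% interval -0.89 to 0.08, limma adjusted p = 0.24, exact permutation p = 0.3) and 0.26 at 5 days (-0.23 to 0.74, limma adjusted p = 0.46, exact permutation p = 0.7). Between the co-cultures it was 0.66 higher at 5 days (0.17 to 1.15, limma adjusted p = 0.096), and every 5-day library lay above every 3-day library, for which the exact two-sided permutation p of 0.1 is the smallest that 3 against 3 libraries can give. Of the 4 tested genes on the list of RUNX and core binding factors, none passed over all genes tested in any comparison, and 1, Runx1 at 5 against 3 days, passed when adjusted over the list alone. The list did not pass camera at 3 days (adjusted p = 0.58), at 5 days (adjusted p = 0.49) or between the co-cultures (adjusted p = 0.082). Between the co-cultures fry passed it, at adjusted p = 0.032. Runx2 (chromosome 17, 44495987 to 44814797, minus strand) had means of 68.5 ± 11 in monoculture, 70.7 ± 12.5 at 3 days and 86.4 ± 15.4 at 5 days (SD, n = 3), and Cbfb (chromosome 8, 105170674 to 105217989, plus strand) had 58.4 ± 28.1, 39.8 ± 18.0 and 46.8 ± 20.2. Runx3 was not among the genes of the deposited counts. The sort gene Pdpn (chromosome 4, 143267431 to 143299564, minus strand) had means of 214.9 ± 20.0, 294.6 ± 83.2 and 275.3 ± 55.0. It did not pass the test in any comparison.

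**Figure D2:**
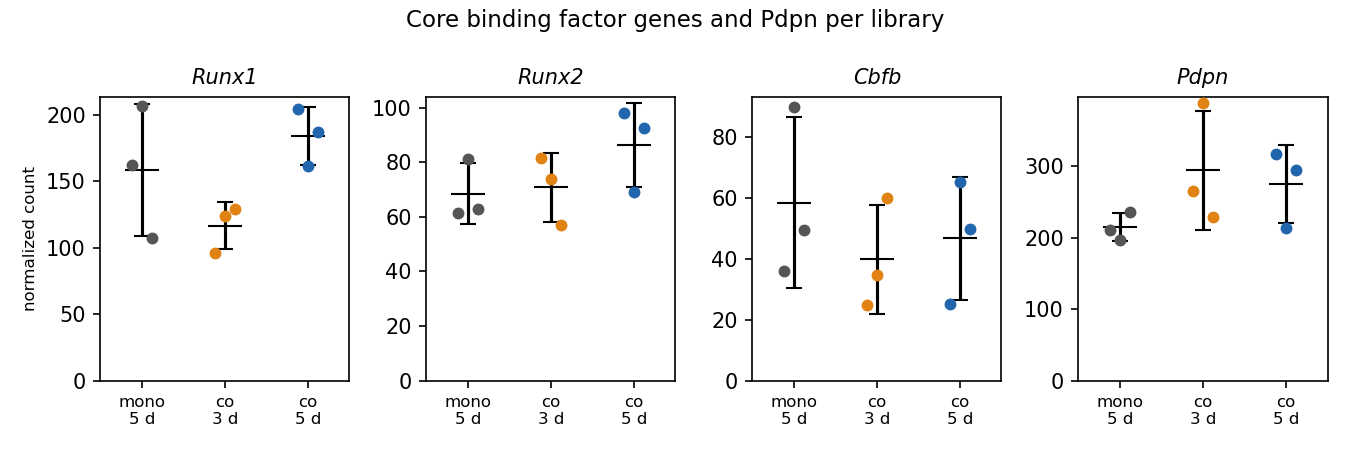
Normalised counts (vertical axis, starting at 0) of Runx1, Runx2, Cbfb and Pdpn in each library, by group, with the mean and SD of 3 libraries as bars. Runx1 lies between 107.3 and 206.2 in monoculture, between 96.3 and 129.4 at 3 days of co-culture and between 161.1 and 204.0 at 5 days.

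In the cells sorted after 3 days with carcinoma cells, the interferon-response genes Isg15, Irf7 and Usp18 were higher than in fibroblasts cultured alone for 5 days. So were the cytokine genes Il1a and Csf2, the stress genes Chac1 and Trib3 and the epithelial markers Wfdc2 and Krt18. The proteoglycan genes Fmod, Prelp and Podn, the collagen-processing gene Pcolce and the adipose progenitor gene Dpt were lower. The largest rises included the epithelial marker Wfdc2, which rose more than Penk, which encodes an enkephalin precursor, and Mmp9, which encodes the protease gelatinase B. The cytokine genes Tnfsf15 and Csf2 were also among them. The largest falls included Figf, an older symbol of the gene for vascular endothelial growth factor D, and Nov, an older symbol of a matricellular protein gene.

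This comparison asks what co-culture for 3 days changed, and co-culture and days in culture differed together, since no monoculture was sampled at 3 days. Of 10639 genes tested with limma, 1132 were higher and 997 lower at an adjusted p under 0.05, and 771 and 611 of these changed at least 2-fold on the log2(value + 1) scale. The count test of edgeR on the recovered reads called 2239 genes, of which 2071 were also called by limma. Mmp9 (chromosome 2, 164940780 to 164955850, plus strand) rose from 49.0 ± 6.6 to 3799 ± 424 normalised counts (SD, n = 3), a log2 fold change of 6.25 ± 0.17 (SE, adjusted p = 7.9e-13). Penk rose from 40.8 to 4332 and Tnfsf15 from 3.33 to 222.3. Csf2 was supported by 1 read in the monocultures against 164, a ratio of 312 with a counting interval from 55.3 to 12400. Figf fell from 1291 to 42.2 and Nov from 1117 to 31.1, a log2 fold change of -5.32, or -5.91 without co-culture replicate 1 at 3 days.

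Of 37 tested interferon-response genes 32 rose and 0 fell (34 rose adjusted over the list alone, camera adjusted p = 2.0e-26, and adjusted p = 0.00046 with an estimated correlation). Isg15 rose from 93.8 ± 13.3 to 1165 ± 91.0, Irf7 from 30.6 to 352.3 and Usp18 from 4.97 to 76.8. Class I antigen presentation genes followed, with 7 of 12 higher and 0 lower (8 higher adjusted over the list alone, camera adjusted p = 0.00012, adjusted p = 0.060 with an estimated correlation), and H2-D1 rose from 643.2 to 1860. H2-D1 belongs to a family of near-identical genes that differ between mouse strains, so its count is uncertain. Among cytokines and chemokines 19 of 30 rose and 4 fell (20 and 5 adjusted over the list alone, camera adjusted p = 5.4e-09, adjusted p = 0.092 with an estimated correlation). Il1a had 0 reads in the monocultures and 104 in co-culture, at least 66.0-fold higher against a floor of 3 counts over the group. Lcn2, which is also on the list of epithelial and carcinoma markers, rose from 6.43 to 269.0, while Cxcl12 fell from 1290 to 94.5. NF-kappa B target genes rose in 11 of 27 cases with 0 lower (12 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0078, adjusted p = 0.091 with an estimated correlation), among them Tnfaip3, from 39.5 to 128.2.

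Epithelial and carcinoma markers were higher in the same libraries: 17 of 21 rose and 1 fell (17 and 1 adjusted over the list alone, camera adjusted p = 3.0e-16, adjusted p = 0.0032 with an estimated correlation). Only 7 of the 21 averaged at least 5 in monoculture. The others needed co-culture libraries to pass the filter on genes, so the share that rose and the camera p are partly set by that filter. Wfdc2 (chromosome 2, 164562413 to 164568510, plus strand) rose from 3.0 ± 3.7 to 320.1 ± 75.5, a log2 fold change of 6.68, or 7.39 without monoculture replicate 2. Krt18 rose from 27.5 to 197.5. Of 7 listed markers of basal or myoepithelial cells 2 were tested, and both rose, with Sfn going from 2.90 to 30.9. Both averaged below 5 in monoculture, so the filter favoured their rise too. The rise of these markers accompanied the rises of the interferon and cytokine genes and the falls of the matrix genes in the co-culture libraries.

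Of 29 tested elastic fibre and matricellular genes 15 fell and 2 rose (17 and 2 adjusted over the list alone, camera adjusted p = 6.9e-09, adjusted p = 0.0093 with an estimated correlation). The proteoglycan genes Fmod, from 487.1 ± 57.1 to 26.3 ± 10.8, Prelp, from 964.0 to 86.8, and Podn, from 391.0 to 41.7, were among them. Of 30 collagen and collagen-processing genes 13 fell and 1 rose (16 and 2 adjusted over the list alone, camera adjusted p = 4.1e-05, adjusted p = 0.10 with an estimated correlation). Pcolce, an enhancer of procollagen cleavage, fell from 2552 to 914.4, whereas Col5a3 rose from 156.8 to 535.7. Col1a1 and Col1a2 did not pass the test, with means of 19220 and 12280 in monoculture and 21440 and 13200 in co-culture, and quantile normalization turned the sign for Col1a2. Adipose progenitor and universal fibroblast genes fell in 13 of 23 cases and rose in 3 (15 and 3 adjusted over the list alone, camera adjusted p = 0.00012, adjusted p = 0.10 with an estimated correlation), and Dpt, the dermatopontin gene, fell from 297.6 to 35.9. General fibroblast markers fell in 5 of 12 cases (5 adjusted over the list alone, camera adjusted p = 0.035, adjusted p = 0.28 with an estimated correlation). That list's call was lost without monoculture replicate 2 (adjusted p = 0.094) and without co-culture replicate 1 at 3 days (0.082), within a range of 0.0068 to 0.094 over its alternatives.

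Genes of the unfolded protein and ATF4 response rose in 14 of 30 cases and fell in 1 (15 and 1 adjusted over the list alone, camera adjusted p = 0.00018, adjusted p = 0.091 with an estimated correlation), with Chac1 rising from 59.6 to 398.4 and Trib3 from 40.1 to 275.7. Immediate early genes fell in 13 of 26 cases and rose in 4 (14 and 5 adjusted over the list alone, camera adjusted p = 0.00081, adjusted p = 0.091 with an estimated correlation), among them Zfp36, from 561.4 to 100.1, and Fos, from 1241 to 257.8. Hypoxia genes fell in 10 of 20 cases and rose in 2 (11 and 2 adjusted over the list alone, camera adjusted p = 0.0035, adjusted p = 0.43 with an estimated correlation), and Egln1 fell from 192.4 to 58.9. Glycolysis genes fell in 6 of 17 cases (7 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.31 with an estimated correlation), including Ldha, from 2237 to 1027. Cell cycle genes fell in 7 of 39 cases (7 adjusted over the list alone, camera adjusted p = 0.0032, adjusted p = 0.48 with an estimated correlation), a call lost without monoculture replicate 3 (adjusted p = 0.19, within a range of 6.7e-05 to 0.19 over its alternatives). In the DNA methylation list 1 of 15 genes rose, Gadd45a, from 163.1 to 1038, and 1 fell, Mbd3, from 370.1 to 215.5 (1 and 1 adjusted over the list alone, camera adjusted p = 0.54). Matrix proteases and their inhibitors went both ways, 6 higher and 5 lower of 33 (6 and 6 adjusted over the list alone, camera adjusted p = 0.93), as did cancer-associated fibroblast markers, 6 higher and 8 lower of 22 (6 and 8 adjusted over the list alone, camera adjusted p = 0.22). Fry passed both lists, at adjusted p = 0.024 for the proteases and adjusted p = 0.00049 for the fibroblast markers.

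**Figure D3:**
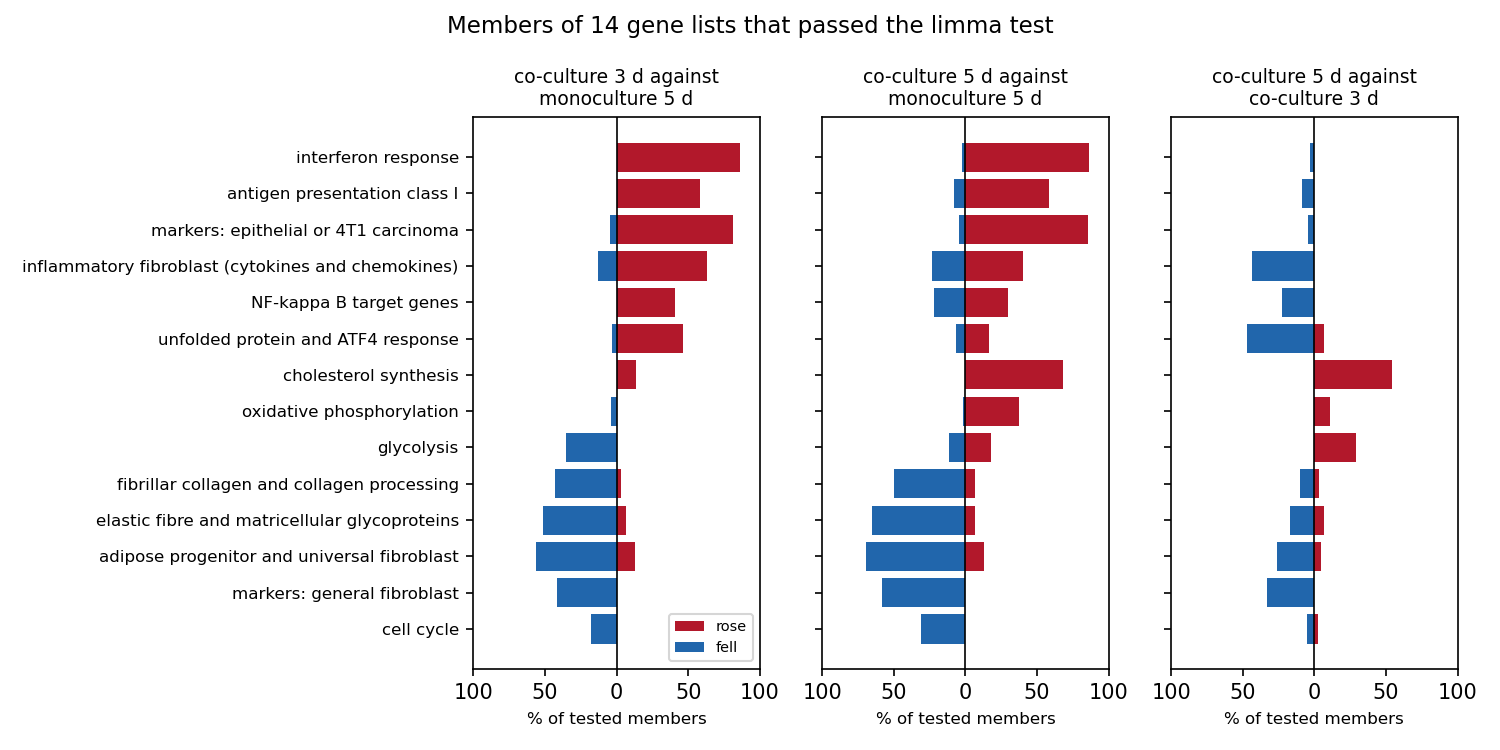
Percent of tested members (horizontal axis, linear) of 14 gene lists that rose (right) or fell (left) at a limma adjusted p under 0.05, in each of the 3 comparisons. Most tested members of the interferon and epithelial lists rise in both comparisons with monoculture, and 13 of 30 cytokine and chemokine genes fall between 3 and 5 days of co-culture.

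In the cells sorted after 5 days of co-culture, set against monoculture of the same age, the interferon-response genes Isg15 and Usp18 and the epithelial markers Wfdc2 and Krt18 were higher. Fmod, Podn, Prelp, Pcolce, Dpt and Ly6a were lower, as were the immediate early genes Nr4a1 and Zfp36. The cholesterol synthesis genes Fdps and Sc5d and the respiratory chain genes Ndufb10 and Cox5a rose. The largest rises included the epithelial marker Wfdc2, Tnfsf15 and Stra6, a receptor gene for retinol-binding protein. The largest falls again included Figf and Nov.

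This comparison asks what co-culture changed at an equal number of days. Limma called 1340 genes higher and 1212 lower of 10639, with 806 and 827 changed at least 2-fold. The count test of edgeR called 2736, of which 2516 were also called by limma. Stra6 (chromosome 9, 58063788 to 58153996, plus strand) had 3 reads in the monocultures against 579, a ratio of 339 with a counting interval from 116 to 1650. Tnfsf15 rose from 3.33 ± 1.45 to 367.0 ± 62.4 (SD, n = 3), a log2 fold change of 6.44 ± 0.27 (SE, adjusted p = 2.4e-10). Figf fell from 1291 to 12.2, a log2 fold change of -6.57 ± 0.23 (adjusted p = 2.5e-11), and Nov fell from 1117 to 14.6, at -6.47, or -7.15 without co-culture replicate 3 at 5 days. Mmp9 rose from 49.0 to 1398 and Mmp10 from 10.1 to 108.3, in a protease list with 9 of 33 higher and 10 lower (9 and 10 adjusted over the list alone, camera adjusted p = 0.96).

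Interferon-response genes rose in 32 of 37 cases and fell in 1 (35 and 1 adjusted over the list alone, camera adjusted p = 4.4e-23, adjusted p = 0.00068 with an estimated correlation). Isg15 rose from 93.8 to 1083 and Usp18 from 4.97 to 102.4. Class I antigen presentation genes rose in 7 of 12 cases and fell in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.021, adjusted p = 0.16 with an estimated correlation), and H2-D1 stood at 1704 against 643.2. Epithelial and carcinoma markers, measured in the same libraries, rose in 18 of 21 cases and fell in 1 (18 and 1 adjusted over the list alone, camera adjusted p = 3.9e-14, adjusted p = 0.0040 with an estimated correlation), with Wfdc2 at 441.4 against 3.0, a log2 fold change of 7.17, or 7.88 without monoculture replicate 2, and Krt18 at 287.1 against 27.5. The filter favoured rises of epithelial markers here too, since only 7 of the 21 averaged at least 5 in monoculture. Both tested basal markers, which also averaged below 5 in monoculture, rose. Cytokine and chemokine genes went both ways, 12 higher and 7 lower of 30 (12 and 8 adjusted over the list alone, camera adjusted p = 0.18). Il1a, with 0 reads in the monocultures and 91 in co-culture, was at least 53.3-fold higher against the floor of 3 counts over the group, while Cxcl12 fell from 1290 to 43.0 and Ccl11 from 238.0 to 15.5. NF-kappa B target genes rose in 8 of 27 cases and fell in 6 (8 and 7 adjusted over the list alone, camera adjusted p = 0.96).

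Cholesterol synthesis genes rose in 15 of 22 cases with 0 lower (17 adjusted over the list alone, camera adjusted p = 2.7e-09, adjusted p = 0.0040 with an estimated correlation). Fdps rose from 177.2 ± 20.3 to 595.8 ± 43.9 and Sc5d from 58.1 to 215.4. Oxidative phosphorylation genes rose in 21 of 56 cases and fell in 1 (23 and 1 adjusted over the list alone, camera adjusted p = 4.2e-06, adjusted p = 0.16 with an estimated correlation), with Ndufb10 going from 386.2 to 798.7 and Cox5a from 453.7 to 1081. Immediate early genes fell in 13 of 26 cases and rose in 4 (14 and 4 adjusted over the list alone, camera adjusted p = 4.2e-06, adjusted p = 0.035 with an estimated correlation), and Nr4a1 fell from 2585 to 429.0 and Zfp36 from 561.4 to 63.4. Cell cycle genes fell in 12 of 39 cases (12 adjusted over the list alone, camera adjusted p = 4.7e-05, adjusted p = 0.42 with an estimated correlation), among them Rrm2, from 86.7 to 18.5. In the DNA methylation list 5 of 15 genes fell and 1 rose (5 and 1 adjusted over the list alone, camera adjusted p = 0.21): Uhrf2 fell from 70.6 to 22.5 and Dnmt3l from 40.6 to 15.1, and Gadd45a rose from 163.1 to 347.3. Fry passed this list at adjusted p = 0.036.

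Elastic fibre and matricellular genes fell in 19 of 29 cases and rose in 2 (20 and 2 adjusted over the list alone, camera adjusted p = 1.1e-10, adjusted p = 0.0040 with an estimated correlation). Fmod fell from 487.1 ± 57.1 to 10.1 ± 3.1, Podn from 391.0 to 8.13 and Prelp from 964.0 to 44.7. Collagen genes fell in 15 of 30 cases and rose in 2 (17 and 2 adjusted over the list alone, camera adjusted p = 4.2e-06, adjusted p = 0.082 with an estimated correlation), with Pcolce at 671.5 against 2552, while Col5a3 rose to 1471 from 156.8. Col1a1 and Col1a2 did not pass the test, with 20910 and 10470 against 19220 and 12280, and the sign for Col1a1 turned under quantile normalization. Adipose progenitor genes fell in 16 of 23 cases and rose in 3 (17 and 3 adjusted over the list alone, camera adjusted p = 4.2e-06, adjusted p = 0.082 with an estimated correlation), including Dpt, from 297.6 to 8.90, and Ly6a, from 837.5 to 27.4. General fibroblast markers fell in 7 of 12 cases (8 adjusted over the list alone, camera adjusted p = 9.1e-05, adjusted p = 0.082 with an estimated correlation). Cancer-associated fibroblast markers rose in 4 of 22 cases and fell in 8 (4 and 9 adjusted over the list alone, camera adjusted p = 0.14), with Pdgfra falling from 189.3 to 21. Fry passed this list at adjusted p = 4.1e-05.

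**Figure D4:**
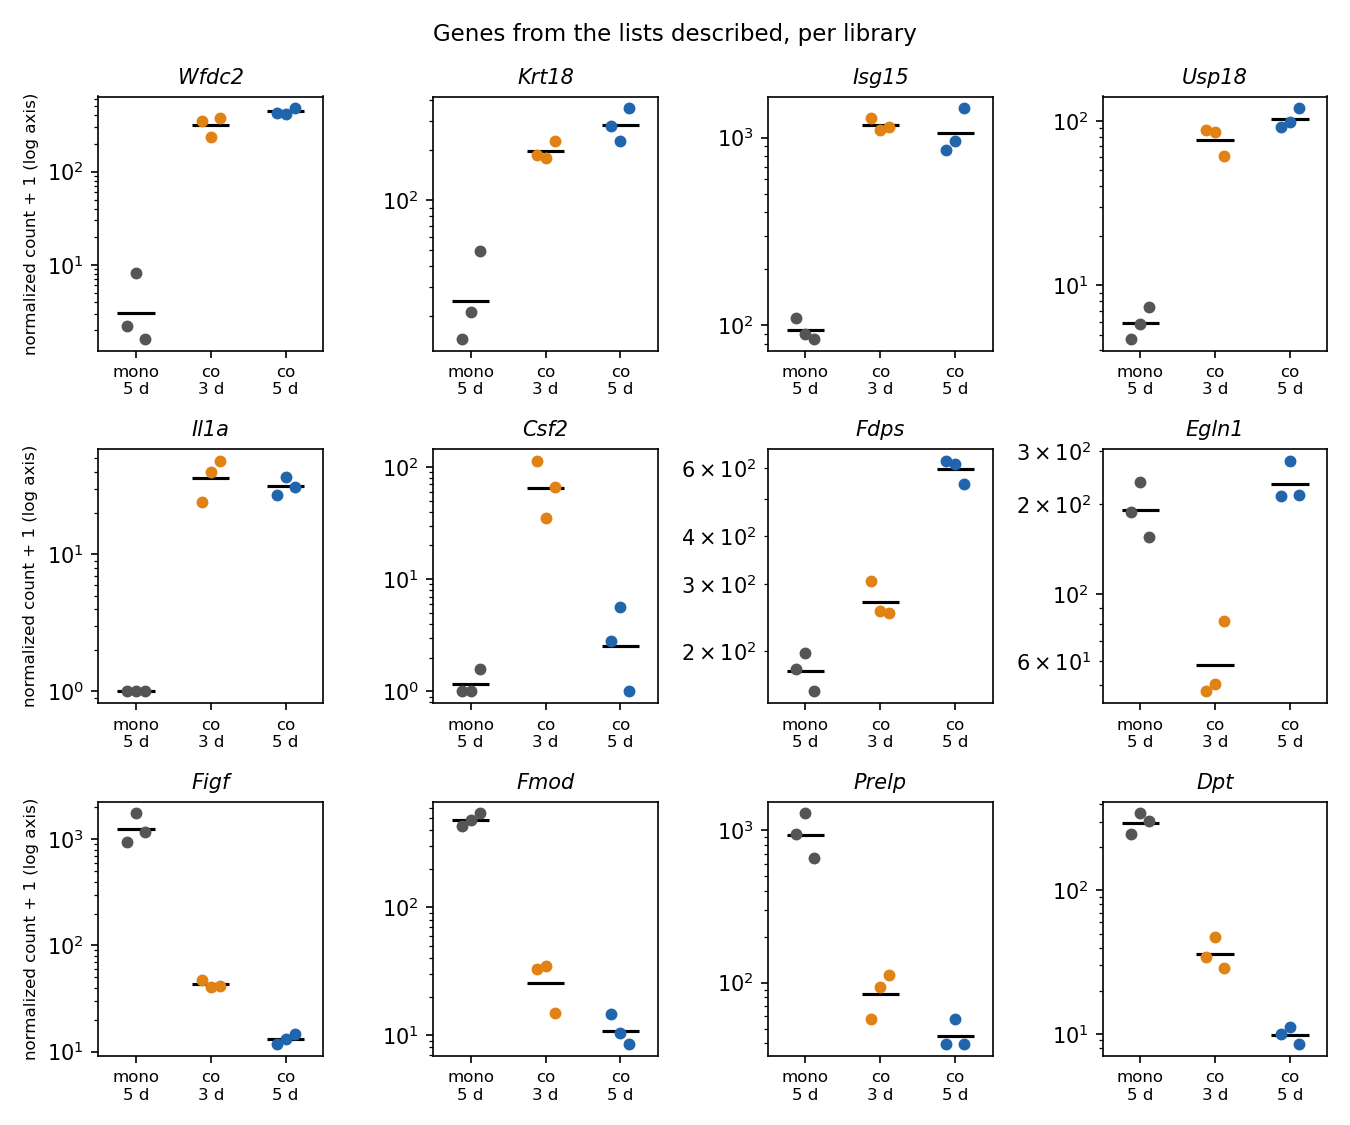
Normalised count plus 1 (log axis) of 12 genes named in the text, with a point per library, and a line at the mean of the log values of 3 libraries. Isg15 and Wfdc2 are high at both times of co-culture, Csf2 is high at 3 days, Fdps is highest at 5 days, and Figf, Fmod, Prelp and Dpt are low in both co-cultures.

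Between 3 and 5 days of co-culture the cytokine and acute-phase genes Csf2, Ccl11, Gdf15 and Saa3 fell, as did the stress genes Asns, Psat1, Hmox1 and Gclm. The cholesterol synthesis gene Fdps, the lactate transporter gene Slc16a3 and the respiratory chain gene Ndufb10 rose. The interferon-response and epithelial lists did not pass the camera test.

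This comparison asks how the co-culture response changed with time, and days of co-culture and total days in culture rose together. Limma called 340 genes higher and 395 lower at 5 days, with 178 and 303 changed at least 2-fold, and DESeq2 called 382 higher and 364 lower. The count test of edgeR called 677, of which 654 were also called by limma. The limma total of 735 fell to 323 without 3-day replicate 2, and to 442, 426 and 458 without 5-day replicates 1, 2 and 3. Without 5-day replicate 2 the split was 148 higher and 278 lower. The largest falls included Csf2, at 2.17 ± 2.37 against 70.8 ± 39.7 (SD, n = 3), a log2 fold change of -4.67 ± 0.61 (SE, adjusted p = 0.00025), or -5.26 and -4.01 without 5-day replicates 2 and 3. Gdf15 fell from 435.3 to 30.3, Saa3 from 12140 to 1020 and Ptx3 from 320.3 to 26.3. Among the largest rises was Nrep, from 4.13 ± 1.27 to 49.9 ± 9.9.

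Cytokine and chemokine genes fell in 13 of 30 cases with 0 higher (19 lower adjusted over the list alone, camera adjusted p = 2.6e-13, adjusted p = 0.072 with an estimated correlation), including Ccl11, from 109.3 to 15.5. NF-kappa B target genes fell in 6 of 27 cases (6 adjusted over the list alone, camera adjusted p = 0.00093, adjusted p = 0.067 with an estimated correlation), with Vcam1 at 28.4 against 140.3 and Cebpb at 308.8 against 665.8. ATF4 and unfolded protein genes fell in 14 of 30 cases and rose in 2 (14 and 5 adjusted over the list alone, camera adjusted p = 0.00041, adjusted p = 0.097 with an estimated correlation), among them Asns, from 813.1 to 234.0, and Psat1, from 320.0 to 80.8. Oxidative stress and NRF2 target genes fell in 7 of 24 cases (7 adjusted over the list alone, camera adjusted p = 2.1e-05, adjusted p = 0.067 with an estimated correlation), with Hmox1 going from 2207 to 735.4 and Gclm from 368.3 to 119.1. Immediate early genes fell in 6 of 26 cases and rose in 2 (11 and 2 adjusted over the list alone, camera adjusted p = 0.00015, adjusted p = 0.075 with an estimated correlation).

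Cholesterol synthesis genes rose in 12 of 22 cases (16 adjusted over the list alone, camera adjusted p = 1.3e-10, adjusted p = 0.0094 with an estimated correlation), with Fdps at 595.8 against 269.5. Glycolysis genes rose in 5 of 17 cases (7 adjusted over the list alone, camera adjusted p = 2.7e-05, adjusted p = 0.17 with an estimated correlation), including the lactate transporter gene Slc16a3, from 432.4 to 1304, and Ldha, from 1027 to 1744. Oxidative phosphorylation genes rose in 6 of 56 cases (21 adjusted over the list alone, camera adjusted p = 2.4e-08, adjusted p = 0.097 with an estimated correlation), with Ndufb10 at 798.7 against 427.2. Hypoxia genes rose in 6 of 20 cases and fell in 1 (7 and 2 adjusted over the list alone, camera adjusted p = 0.0041, adjusted p = 0.41 with an estimated correlation). Egln1 rose from 58.9 to 234.7 and Ankrd37 from 2.97 to 16.2, while Adm fell from 93.5 to 27.6, and the list's call was lost without 5-day replicate 2 (adjusted p = 0.052, within a range of 0.0012 to 0.052 over its alternatives). Interferon-response genes fell in 1 of 37 cases, Zbp1, from 213.4 to 78.6 (1 adjusted over the list alone, camera adjusted p = 0.72), and epithelial markers fell in 1 of 21 cases (1 adjusted over the list alone, camera adjusted p = 0.73).

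Elastic fibre and matricellular genes fell in 5 of 29 cases and rose in 2 (9 and 2 adjusted over the list alone, camera adjusted p = 0.0099, adjusted p = 0.097 with an estimated correlation), and Podn fell from 41.7 to 8.13. General fibroblast markers fell in 4 of 12 cases (6 adjusted over the list alone, camera adjusted p = 0.0019, adjusted p = 0.11 with an estimated correlation). Adipose progenitor genes fell in 6 of 23 cases and rose in 1, Wnt2, from 30.9 to 119.3 (6 and 2 adjusted over the list alone, camera adjusted p = 0.015, adjusted p = 0.23 with an estimated correlation), a call lost without 3-day replicate 3 (adjusted p = 0.10) and without 5-day replicate 1 (0.065), within a range of 0.0020 to 0.10 over its alternatives. Collagen genes fell in 3 of 30 cases and rose in 1 (4 and 1 adjusted over the list alone, camera adjusted p = 0.18), the riser being Col5a3, from 535.7 to 1471. Mmp9 fell from 3799 to 1398 and Gadd45a from 1038 to 347.3. Of 22 cancer-associated fibroblast markers 5 fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.075), and Vim rose from 4803 to 11040. Fry passed this list at adjusted p = 0.0022.

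The responses at 3 and 5 days shared many genes. Of the genes called in both comparisons with monoculture, 728 were higher at both times, 595 were lower at both times and 12 changed in opposite directions. Independent lists of the same sizes would share 142.6 and 113.6 genes. Across the 10639 genes, which are not independent replicates, the log2 fold changes had Pearson's r of 0.79 and Spearman's rho of 0.71, against a simulated r of 0.50 for unchanged groups set against the same monoculture libraries. The covariance was 0.678 against a simulated 0.0586, a difference of 0.619, and the 50 simulations gave on average 0.02 genes called in the same direction. Since the simulated groups held no changed genes, almost none could be called, so this count is not a chance level for lists of these sizes. The 3 shared monoculture libraries could not be split into parts of at least 2, so part of the excess over independent lists may come from them.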

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

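The tests of carcinoma RNA in a single profile, of dilution and of a smaller carcinoma share, and the thinning of reads, were chosen after the results were seen. The epithelial and matrix patterns below were changes seen in both co-cultures. What drew attention to the cytokine list and to the further genes and lists was a difference between the responses at 3 and 5 days. That difference was tested as the 5-day against 3-day contrast.

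Epithelial markers were higher in both co-cultures, with 17 of 21 tested markers called higher at both times. After thinning every library to the depth of the shallowest, 16 were called higher at both times, so these calls did not rest on unequal depth. The co-culture libraries were the shallower ones, so depth was a weak candidate for rises from the start. RNA of carcinoma cells that passed the sort against GFP is a candidate explanation: in a single profile on both days the 5-day against 3-day changes of 15 markers held by no other list would be equal, and their heterogeneity p of 0.053 (SD 0.45, median SE 0.41) lay just above 0.05, which does not show that they were equal. The most abundant markers, Wfdc2 and Krt18, averaged 441.4 and 287.1 normalised counts at 5 days. Of the 21 markers, 7 already averaged at least 5 in monoculture, and 2, Lcn2 and Perp, are held by another list. Markers below 5 in monoculture passed the filter on genes only with the help of co-culture libraries, which favours rises. Expression by the fibroblasts themselves, which the co-culture groups also allow, was not tested and stays open.

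Matrix genes were lower in both co-cultures, with 14 of 29 elastic fibre and matricellular genes called lower at both times. After thinning, 13 were called lower at both times, which argues against depth. Dilution of fibroblast RNA by RNA of other cells would lower every fibroblast marker by about the list's median of -1.28 at 5 days, but 5 of the 12 general fibroblast markers (Col1a1, Col1a2, Fbn1, Mfap5 and Pdpn) had 95% intervals wholly above it. Fbn1 and Mfap5 also belong to the list that set this median, and Pdpn was the sort gene, so these were not independent of the list or the sort. Col1a1, at 0.12 (95% interval -0.41 to 0.65), and Col1a2, at -0.23 (-0.65 to 0.19), did not fall by that amount. For Col1a1 and Col1a2 a uniform dilution of that size is unlikely, but dilution as part of the cause was not excluded. A change of fibroblast state, or of which fibroblasts survived or passed the podoplanin sort in co-culture, was not tested and stays open.

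Of 30 cytokine and chemokine genes 13 were lower at 5 than at 3 days of co-culture, with a list median of -1.08. If the epithelial markers were carcinoma RNA, a smaller share of it at 5 days would lower them alike. The median of 16 markers, without Lcn2, which is on both lists, lay 1.15 above that of the cytokine list. The SD among the markers was 0.47. Since the source of the markers stays open, this comparison cannot exclude carcinoma RNA as part of the cytokine fall. At the preset correlation no library decided the result alone, since the largest adjusted camera p over 6 leave-outs was 7.6e-10, but the call was lost at adjusted p = 0.072 with an estimated correlation. A change of the fibroblasts with time in co-culture, and days in culture, for which no 3-day monoculture was analysed here, were not tested and stay open.

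Beside these, further genes and lists had responses to co-culture that differed between the days at a limma adjusted p under 0.05. Lower at 5 than at 3 days (log2 fold change) were Csf2 at -4.67, Ccl11 at -2.79, Lcn2 at -1.42 and Cxcl12 at -1.10. Lcn2 no longer passed without 3-day replicate 2 (-1.25) or 5-day replicate 2 (-1.18), with adjusted p from 3.3e-05 to 0.090 over its alternatives. Cxcl12 no longer passed without 3-day replicates 2 (-1.10) and 3 (-0.92) or 5-day replicates 1 (-1.06) and 3 (-1.01), with adjusted p from 0.011 to 0.10. The matrix and fibroblast genes Podn at -2.28, Ly6a at -2.00, Dpt at -1.87, Nid2 at -1.85, Pdgfra at -1.26, Fmod at -1.24, Itga11 at -0.74 and Thy1 at -0.72 were lower too. Fmod no longer passed without 3-day replicates 1 (-1.06) and 2 (-1.02) or 5-day replicates 2 (-1.20) and 3 (-1.06), with adjusted p from 0.0019 to 0.12. Thy1 no longer passed without 3-day replicates 1 (-0.62) and 2 (-0.70) or 5-day replicates 1 (-0.71) and 2 (-0.72), with adjusted p from 0.00084 to 0.075. Itga11 no longer passed when any of the 6 libraries was left out, at -0.71, -0.83 and -0.67 without 3-day replicates 1, 2 and 3 and -0.72, -0.80 and -0.70 without 5-day replicates 1, 2 and 3, with adjusted p from 0.019 to 0.095. So were the growth factor and peptide genes Sfrp1 at -1.99, Figf at -1.71 and Penk at -1.31. Penk no longer passed without 3-day replicates 2 (-1.27) and 3 (-1.03) or 5-day replicate 3 (-0.92), with adjusted p from 0.0013 to 0.077. Mmp9 at -1.44, Dnmt3l at -1.29, Gadd45a at -1.60, Trib3 at -1.49, Chac1 at -1.28 and Nr4a1 at -1.08 were also lower. Dnmt3l no longer passed without 3-day replicate 2 (-1.23) or 5-day replicate 3 (-1.17), with adjusted p from 0.0079 to 0.076.

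Higher at 5 than at 3 days were Egln1 at 2.01, Wnt2 at 1.92, Mmp10 at 1.68, Stra6 at 1.62, Col5a3 at 1.46, Fdps at 1.14, Ndufb10 at 0.90 and Ldha at 0.76. Mmp10 no longer passed without 3-day replicate 2 (1.43), with adjusted p from 0.00015 to 0.064, nor Stra6 without 5-day replicate 1 (1.47), with adjusted p from 2.1e-06 to 0.054. Among gene lists, tested with camera at the preset correlation, the medians were 1.10 for cholesterol synthesis, 0.68 for glycolysis, 0.43 for hypoxia response and 0.36 for oxidative phosphorylation. Of these only cholesterol synthesis also passed with an estimated correlation, at adjusted p = 0.0094, against adjusted p = 0.17, 0.41 and 0.097 for the other 3 in that order. Medians below 0 were -0.77 for adipose progenitor genes, -0.71 for the unfolded protein and ATF4 response, -0.53 for general fibroblast markers, -0.45 for immediate early genes, -0.33 for NF-kappa B target genes and -0.24 for elastic fibre and matricellular genes. With an estimated correlation none of these 6 passed, at adjusted p = 0.23, 0.097, 0.11, 0.075, 0.067 and 0.097 in that order. At the preset correlation hypoxia response no longer passed without 5-day replicate 2 (adjusted p = 0.052, range 0.0012 to 0.052), nor adipose progenitor genes without 3-day replicate 3 (adjusted p = 0.10, range 0.0020 to 0.10) or 5-day replicate 1 (0.065).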

How the results depend on the processing

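Of 122 results of genes selected for a comparison and 41 list results, 111 and 35 kept their direction and their side of the threshold under every alternative tried, which were 14 settings for genes and 12 for lists, among them the thinning chosen after seeing the data, and the removal of each library. These leave out 5-day against 3-day values of genes selected for another comparison, of which Lcn2, Cxcl12, Fmod, Penk, Itga11, Thy1, Dnmt3l, Mmp10 and Stra6 lost the call without a library. Most of the genes were chosen for large or clear changes, and the lists for passing camera. Such stability is therefore partly built in and does not describe the other called genes. Runx1 did not pass the threshold under any alternative, with log2 fold changes from -0.66 to -0.19 at 3 days, 0.0030 to 0.47 at 5 days and 0.53 to 0.75 between the co-cultures. No scaling moved the median of all genes by over 0.1 on the log2 scale. The added 2-fold threshold lowered the counts of called genes from 2129 to 1382 at 3 days, from 2552 to 1633 at 5 days and from 735 to 481 between the co-cultures, and the shared calls from 1323 to 863, by construction. Array weights raised the count between the co-cultures to 1124, and thinned reads lowered it to 484; for the weights the cause was not tested, and thinning removes reads. Leaving out a library gave 323 to 693 genes there, with fewer libraries in the fit.

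Genes that were not called turned sign. Under quantile normalization Col1a2 at 3 days stood at -0.22 and Col1a1 at 5 days at -0.22. Leaving out libraries gave Runx2 at 3 days -0.031 (monoculture replicate 1), -0.012 (monoculture 3) and -0.066 (co-culture 1), against up to 0.19 without co-culture 3. Cbfb at 5 days turned to 0.045 (monoculture 2) and 0.069 (co-culture 1), against -0.61 without monoculture 1, and between the co-cultures to -0.067 (3-day 1) and -0.070 (5-day 2). Col1a1 at 5 days turned to -0.021 (monoculture 1) and -0.013 (co-culture 2), against 0.32 without co-culture 3, and Pdpn between the co-cultures to 0.14 (3-day 2) and 0.092 (5-day 2), against -0.24 without 3-day 3. The cause was not tested. Pdpn at 3 days passed the threshold under array weights alone, at 0.60 (limma adjusted p = 0.027, range 0.027 to 0.58).

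Settings that kept every library also ended list calls of camera. General fibroblast markers at 3 days were lost in the fit of only the compared groups (adjusted p = 0.057) and under array weights (0.064), within 0.0068 to 0.094 over all alternatives. Between the co-cultures TGF-beta genes were lost with a mean of at least 20 (adjusted p = 0.057) and under quantile normalization (0.070), within 0.013 to 0.095. Adipose progenitor genes were lost with a mean of at least 20 (adjusted p = 0.099, within 0.0020 to 0.10), and chaperone genes under quantile normalization (adjusted p = 0.058, within 0.0030 to 0.058). The added 2-fold threshold removed Mbd3 at 3 days and Ldha, Pmepa1 and Ndufb10 between the co-cultures, by construction.

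The replicate numbers were not taken to pair the libraries: the deviations of libraries with the same number correlated between -0.11 and 0.23, with 0.13, 0.14 and 0.17 for number 1. The own number correlated best in 8 of 18 pairs of a library and another group, and for 2 of 9 libraries overall. With the replicate block, 2219, 2663 and 827 genes were called and 1387 were shared, and no call among 167 results changed.

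Of the 10 splits of 6 libraries in each comparison, 1, the real grouping, gave 2129, 2552 or 735 genes, and the highest of the others gave 0 in each. A share under 0.05 is out of reach with 10 splits. Depth limits what can be seen of genes with few reads, since the shallowest library holds 1048471.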

Other observations

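Genes for secreted growth factors and their antagonists changed in both directions at 5 days against monoculture, with 12 higher and 16 lower of 44 (13 and 19 adjusted over the list alone, camera adjusted p = 0.25). Sfrp1, a Wnt antagonist gene, fell from 5294 ± 1198 to 244.1 ± 131.0 normalised counts (SD, n = 3), while Wnt2 rose from 4.93 to 119.3. The activin gene Inhba rose from 1401 to 11300 and Ctgf, an older symbol of a matricellular gene, rose from 1288 to 4607, whereas Id1 fell from 1536 to 166.7, in a TGF-beta list with 10 of 27 higher and 5 lower (11 and 5 adjusted over the list alone, camera adjusted p = 0.42). Between the co-cultures 3 of those 27 rose, among them Tgfbr1, from 114.9 to 256.8, and Pmepa1, from 280.2 to 480.4 (3 adjusted over the list alone, camera adjusted p = 0.028, adjusted p = 0.097 with an estimated correlation). That call was lost without 3-day replicate 2 (adjusted p = 0.095) and without 5-day replicate 3 (0.068), within a range of 0.013 to 0.095 over its alternatives. Contractile genes rose in 6 of 21 cases and fell in 4 (7 and 4 adjusted over the list alone, camera adjusted p = 0.81), with Pdlim7 rising from 287.1 to 715.7 and Itga11 falling from 1227 to 174.9 and Thy1 from 2588 to 930.9, and Tagln was lower at 5 than at 3 days, at 1723 against 4952. Basement membrane genes rose in 2 of 16 cases and fell in 2 (2 and 2 adjusted over the list alone, camera adjusted p = 0.96): Agrn rose from 76.2 to 316.1 and Col15a1 from 101.5 to 349.0, and Nid2 fell from 164.0 to 21.2.

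Genes of p53 and senescence rose in 8 of 22 cases at 3 days and fell in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.0016, adjusted p = 0.17 with an estimated correlation). At 5 days 8 rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.090), with Cdkn2b rising from 107.9 to 560.4 and Btg2 falling from 321.7 to 71.3. Ribosomal protein genes rose in 11 of 57 cases at 5 days and fell in 4 (11 and 4 adjusted over the list alone, camera adjusted p = 0.055), and Rps24 rose from 3113 to 6822. Chaperone genes rose in 2 of 24 cases between the co-cultures (6 adjusted over the list alone, camera adjusted p = 0.0099, adjusted p = 0.097 with an estimated correlation), a call lost without 3-day replicate 3 (adjusted p = 0.051, within a range of 0.0030 to 0.058). Growth factor genes between the co-cultures rose in 5 cases and fell in 9 of 44 (6 and 10 adjusted over the list alone, camera adjusted p = 0.0078, adjusted p = 0.097 with an estimated correlation).

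Apart from the epithelial and fibroblast markers, the cell type lists large enough for camera did not pass it at 5 days, although single members changed. At 5 days against monoculture, camera adjusted p-values were 0.97 for macrophage or leukocyte markers (0 higher and 1 lower of 10, and 0 and 1 adjusted over the list alone), 0.49 for endothelial markers (1 higher of 4, and 1 adjusted over the list alone), 0.22 for pericyte or smooth muscle markers (1 higher of 5, and 2 adjusted over the list alone), 0.090 for adipocyte markers (1 lower of 3, and 1 adjusted over the list alone) and 0.96 for Schwann cell or muscle markers (1 higher of 4, and 1 adjusted over the list alone). Of class II antigen presentation genes 2 were tested and 1 fell at 5 days (1 adjusted over the list alone), of mesothelial markers 1 was tested and rose (1 adjusted over the list alone), and no mitochondrially encoded gene was in the table. For some lists without a call, the median, the mean or the camera direction differed in sign. These were proteases in every comparison, growth factors at 3 days, and, at 5 days, contractile, NF-kappa B, glycolysis, hypoxia, chaperone, macrophage and Schwann cell or muscle genes.

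The fall of Id1 prompted the hypothesis that targets of bone morphogenetic protein (BMP) signalling fall together in co-culture. A set of 15 BMP target genes outside the fixed lists, written down before its values were seen, had 6 tested members. At 3 days 0 of these rose and 1 fell, Atoh8, with a log2 fold change of -3.18. At 5 days 1 rose, Heyl, at 3.51, and 2 fell, Atoh8 at -3.97 and Gata2 at -1.18. Their median log2 fold change was -0.23 at 3 days and -0.27 at 5 days, and camera gave an adjusted p = 0.22 and an adjusted p = 0.31 (adjusted over the 2 comparisons). The hypothesis needed a median under -0.5 and a p under 0.05 at both times, so the test came out negative for this set. The set left out Id1 and every other gene of the TGF-beta list by design. Id4, an Id gene that was in neither the set nor the TGF-beta list, was also lower in co-culture. Its normalised counts were 112, 175.9 and 96.4 in monoculture, 5, 4.2 and 7 at 3 days, and 1.8, 1.9 and 0 at 5 days. With 6 tested members that went both ways, the result does not decide whether BMP targets outside the set fell.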
